A study of Mus musculus with 3 samples.

How the data were processed

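Brain cells sorted as CD45hi from naive wild-type, infected wild-type and infected CCR2-DTR mice were available as 3 single-cell libraries, 1 per group. Per the submitters' processing notes, the authors made the deposited counts with bcl2fastq 2.20.0.422 and Cell Ranger 2.1.0 on the mouse genome mm10, so each deposited value is a count of unique molecular identifiers (UMIs) for a gene and a barcode. Each deposited matrix was unfiltered and listed 737280 barcodes and 27998 genes. The labels' extraction protocol describes a bulk preparation with poly(A) selection, which differs from the barcode-by-gene form of the files, and the values were handled as the files show them. The authors' annotation version is not given in the sources used here. Gene positions were taken from GENCODE mouse release M21 by Ensembl identifier. T cell receptor constant genes and most immunoglobulin constant genes are not among the deposited genes.

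Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs. Of 907, 1889 and 1850 barcodes at the UMI minimum in the naive, wild-type infected and CCR2-DTR infected libraries, 3, 3 and 12 fell to the gene minimum and 13, 83 and 33 to the mitochondrial limit. Scrublet called 7, 3 and 6 further barcodes as doublets at an expected rate of 0.008 per 1000 cells, that is 0.786%, 0.166% and 0.332% against an expected 0.713%, 1.44% and 1.44%, so doublets may remain in the infected libraries. This left 884, 1800 and 1799 cells. A further 593, 662 and 488 barcodes held 200 to 499 UMIs and were left out. Cells were scaled to 10000 UMIs, log-transformed and clustered together without integration in scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, seed 0), with anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 on Python 3.11.15. Figures were drawn with matplotlib 3.10.9. A cluster was named after its best-scoring marker list when that list scored at least 1 and at least 3 markers of the class were raised. No other class could have more markers among the top 10 genes of the cluster. A class with none of its markers there could thus still be named when no other class had any. Clusters with cell-cycle genes as the best list, and others not named, kept a number.

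Free RNA was the summed profile of barcodes with 1 to 50 UMIs (818751, 1844237 and 1673796 UMIs). Its share of the UMIs in B cell-like and T cell-like cells, estimated from neutrophil markers, was 4.85%, 9.49% and 7.68%. It was not subtracted in the values reported, except in the alternative settings and where the text says so. Neutrophil markers made up 10.7%, 2.76% and 11.9% of it.

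Levels are UMIs of a gene summed over the cells of a class, relative to all UMIs of the class (CPM). Shares have Clopper-Pearson, levels exact Poisson, and ratios exact conditional binomial 95% intervals. With 1 library per group no test between groups was made, and these intervals cover the counting of UMIs or cells and nothing else. Those of levels and their ratios take the UMIs of a cell as independent, so variation between cells of a library is left out. A ratio against 0 UMIs is given as a lower bound, with 3 UMIs in place of 0. Classes with at least 100 kept cells in both libraries were compared as planned, and those with at least 50 on a minimum added after the data were seen. For each of 25 gene lists fixed in advance, the median log2 ratio (prior of 10 CPM) was taken over members with at least 20 CPM in at least 1 library, for lists with at least 5 such members. It was placed among 10000 random lists matched on level. Members at least 1.5-fold higher or lower were counted, and 1000 counting resamples gave the spread.

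Genes named in the text followed a rule set beforehand. In each of the 4 classes with most cells, the 4 highest and 4 lowest ratios were taken among genes with at least 100 CPM, a UMI in at least 10% of cells and at least 0.5 times their free-RNA level in the higher library. Mitochondrial, ribosomal protein, haemoglobin, Y-linked, antigen receptor variable and unnamed genes and Xist were left out. Ccr2 and up to 4 members of each described list at 1.5-fold or more in the list's direction, with highest mean CPM, were added. The classes compared on the added minimum used the same rule. Members named beyond this (Mrc1, Ear2, Isg15, S100a8 and the genes and marker levels of the closing section) were chosen after their values were seen. Some genes that the rule takes are not reported here.

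Intervals and list medians were tested on simulated data made from the means of 3 of the compared classes. Intervals held the simulated fold in 96 to 98% of genes per fold for neutrophil-like cells (CCR2-DTR against wild-type infected, 3620 genes), 92 to 98% for T cell-like cells (same comparison, 4968 genes) and 96 to 98% for B cell-like cells (infected against naive, 5160 genes). Lists of unchanged genes fell outside the central 95% in 4%, 2% and 2% of 50 draws. The simulated counts were Poisson, the model behind the intervals, so coverage near 95% was largely set in advance. They hold no variation between cells, so this checks the computation and not whether the intervals are wide enough for real cells.

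Alternatives covered the UMI minimum, the mitochondrial limit, doublets, the clustering resolution, TMM and median-of-ratios factors computed with edgeR 4.0.16 in R 4.3.3, the prior, the low-level filter, thinning of cells to 500 UMIs and subtraction of the free RNA. The added ones were the class minimum of 50 cells and shares computed without neutrophil-like cells or without these and cluster 14. Plasmacytoid dendritic cell-like, basophil or mast cell-like, natural killer cell-like and Gata3 and Il1rl1 lymphocyte-like cells were too few for ratios of gene levels, and cluster 6 and cluster 14 were not compared between groups beyond their shares.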

Results

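Single brain leukocytes sorted as CD45hi were profiled by 10x droplet sequencing from adult C57BL/6 mice in 3 groups, with 1 library per group. The groups were naive wild-type mice, wild-type mice 8 days after infection with the nematode Trichinella spiralis, and CCR2-DTR mice depleted of monocytes at the same time after infection. The libraries held 2212944, 5845542 and 6891245 UMIs in that order. After filtering, 884, 1800 and 1799 cells remained, holding 49.3%, 54.9% and 67.8% of the UMIs. The median depth per kept cell was 996, 1332 and 1985 UMIs, so a gene was seen in more cells of the CCR2-DTR library at the same level. With a single library per group, no difference below has a test or a p-value. Intervals in parentheses are 95% intervals covering counting error only, so differences between mice, sorts and sequencing runs are not in them. For gene levels and their ratios, variation between cells of a library is not in them either.

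Ccr2, the chemokine receptor that marks inflammatory monocytes and that the depletion acts through, was read first as a check of the labels (ENSMUSG00000049103, mm10, chromosome 9, 124101950 to 124113557). Over all kept cells it stood at 324 CPM (292 to 360) in the naive library, 537 CPM (511 to 562) in the wild-type infected library and 18.6 CPM (14.9 to 22.96) in the CCR2-DTR infected library, from 354, 1721 and 87 UMIs. Cells with a Ccr2 UMI made up 17.3%, 33.7% and 3.06% of the kept cells, and 9.95%, 16.3% and 0.723% once every cell was thinned to 500 UMIs. B cell-like cells, which should lack the gene, held a Ccr2 UMI in 0.685%, 4.33% and 0.578% of cells, or 0.685%, 1.44% and 0.289% after thinning, at median depths of 848.5, 852 and 1393 UMIs. The low Ccr2 of the CCR2-DTR library went in the direction of its label. Xist, the X-inactivation RNA of female cells, was present in all libraries at 829, 1079 and 665 CPM, and the Y-linked genes Ddx3y, Eif2s3y and Uty had 0 UMIs.

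The 4483 kept cells fell into 17 clusters, of which 15 were named from marker lists fixed in advance. They gave neutrophil-like cells, classical and non-classical monocyte-like cells, a mixed dendritic cell or macrophage-like class, plasmacytoid dendritic cell-like, microglia-like, basophil or mast cell-like, natural killer cell-like, T cell-like and B cell-like cells, and a class of lymphocyte-like cells with Gata3 and Il1rl1. Gata3 is the master regulator of type 2 lymphocytes and Il1rl1 encodes the IL-33 receptor. A pair of clusters stayed unnamed: cluster 6, with cell-cycle genes as its best-scoring list, and cluster 14, with microglial genes but none of the microglia list among its strongest markers. All shares are of CD45hi-sorted barcodes with at least 500 UMIs, so they depend on that sort and that minimum and are not numbers of cells in the brain.

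**Figure D1:**
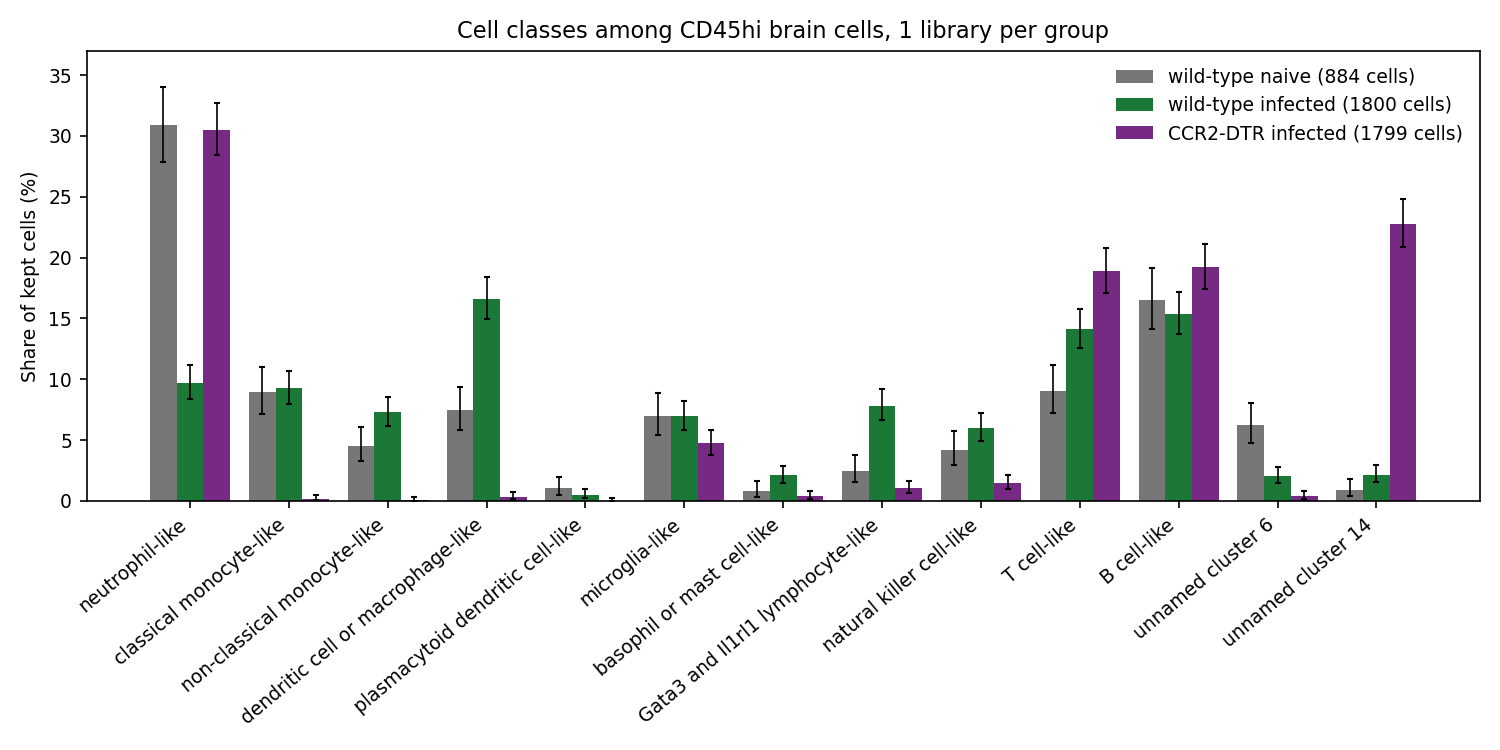
Share of each cell class among kept CD45hi cells in the 3 libraries, with 95% intervals covering counting error only. Cluster 6 and cluster 14 met no naming rule.

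The first comparison, wild-type infected against wild-type naive, asks which leukocytes of the brain differ 8 days after infection by a worm that lives in gut and muscle. Dendritic cell or macrophage-like cells and Gata3 and Il1rl1 lymphocyte-like cells made up larger shares of the infected library, and neutrophil-like cells a smaller one. Genes of alternative macrophage activation, the program driven by IL-4 and IL-13, were much higher in the dendritic cell or macrophage-like class: the eosinophil-attracting chemokine Ccl24 had 516 UMIs against 0, and Retnla was 65.8-fold higher (25.7 to 242). Interferon-gamma-induced genes were higher in classical monocyte-like and neutrophil-like cells, and T cell-like cells held more of the type I interferon response. Microglia-like cells held less Apoe, Cd9 and other genes of the disease-associated microglia list, and Apoe was also lower in the dendritic cell or macrophage-like class.

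The dendritic cell or macrophage-like class (clusters 2 and 10) was 7.47% (5.82 to 9.40) of naive and 16.6% (14.9 to 18.4) of infected cells, from 66 and 299 cells, a ratio of 2.22 (1.70 to 2.95). Gata3 and Il1rl1 lymphocyte-like cells were 2.49% (1.57 to 3.74) and 7.83% (6.63 to 9.17), from 22 and 141 cells, a ratio of 3.15 (1.999 to 5.18). Non-classical monocyte-like cells were 4.52% and 7.28% (1.61, 1.12 to 2.35), T cell-like cells 9.05% and 14.1% (1.56, 1.21 to 2.03), and basophil or mast cell-like cells 0.792% and 2.11% (2.67, 1.18 to 7.08). Natural killer cell-like cells had a share ratio of 1.43 (0.979 to 2.14). Classical monocyte-like cells were 8.94% and 9.28% (1.04, 0.790 to 1.37), microglia-like cells 7.01% and 6.94% (0.990, 0.725 to 1.37), and B cell-like cells 16.5% and 15.4% (0.932, 0.760 to 1.15). Neutrophil-like cells were 30.9% (27.8 to 34.0) of the naive library, with 251, 17 and 5 cells in clusters 0, 12 and 16. In the infected library they were 9.72% (8.39 to 11.2), with 159, 7 and 9 cells in the same clusters, a share 3.18-fold lower (2.62 to 3.86). Shares within a library sum to a fixed total, so a lower neutrophil share alone raises the others. With neutrophil-like cells left out, the log2 ratio was 0.77 for dendritic cell or macrophage-like (1.15 with them), 1.27 for Gata3 and Il1rl1 lymphocyte-like (1.65), 0.26 for T cell-like (0.64) and -0.49 for B cell-like cells (-0.10). The T cell-like value was not stable, at 0.027 with a minimum of 1000 UMIs and 1.75 with called doublets kept, where the Gata3 and Il1rl1 lymphocyte-like value was 0.96.

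In the dendritic cell or macrophage-like class, the alternative activation list had a median log2 ratio of 2.83 in infected against naive cells, with 14 of 16 members at least 1.5-fold higher and 1 lower, above 100% of matched random lists. The makeup of the class differed too, so changes within a cell type were not separated from changes in the mix. From naive to infected, markers of border-associated macrophages stood at 1564 and 579.6 CPM. Those of monocyte-derived macrophages or dendritic cells stood at 22033 and 6273 CPM. They include Apoe, C1qa and C1qb, all lower in this class, so their sum does not measure the share of such cells. Markers of mature migratory dendritic cells, whose cluster has Ccl17 among its top genes, stood at 467 and 1846 CPM. The highest genes of the list were Ccl24 (ENSMUSG00000004814, chromosome 5, 135569937 to 135573049; 614 CPM, UMI in 15.7% of cells, at least 20.2-fold higher), Retnla (2673 against 40.6 CPM), the Th2-attracting chemokine Ccl17 (33.0-fold, 12.9 to 121), and Arg1, the enzyme that breaks down arginine, with 144 UMIs against 0 (at least 5.62-fold). Ear2 (12.0-fold, 5.48 to 32.8), the fibronectin gene Fn1 (8.01-fold, 4.19 to 17.6) and the chitinase-like Chil3 (7.50-fold, 4.05 to 15.7) followed. The mannose receptor gene Mrc1, another member, stood at 376 against 345 CPM. Interferon-gamma-induced genes had a median of 1.14 (12 of 16 higher, 2 lower), with Gbp2 at 8.32-fold (1.45 to 333) on 71 against 1 UMI. Oxidative phosphorylation (median 0.71, 9 of 17 higher, 1 lower; Cox5b 2.24-fold, 1.47 to 3.57) and glycolysis genes (8 of 15 higher, 1 lower; Gapdh 2.57-fold, 1.56 to 4.55; Pkm 4.43-fold, 1.86 to 13.8) were also higher, as was MHC class I presentation (median 0.58, 9 of 16 higher; H2-K1 1.94-fold, 1.54 to 2.47).

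The same class held less of several resident macrophage and stress genes after infection. The homeostatic microglia list had a median of -0.92 (8 of 14 lower, none higher), including Cx3cr1 at a ratio of 0.431 (0.326 to 0.576) and Csf1r at 0.575 (0.450 to 0.744). Complement genes had a median of -0.52 (5 of 11 lower, 3 higher), with C1qa at 0.351 (0.293 to 0.421), C1qb at 0.323 (0.269 to 0.390) and C1qc at 0.299 (0.249 to 0.361). Apoe, a lipid carrier, stood at 0.180 (0.169 to 0.192). NF-kB and inflammatory cytokine genes (median -0.67, 8 of 15 lower, 1 higher) included the LPS co-receptor Cd14 at 0.210 (0.125 to 0.362) and Nfkbiz at 0.314 (0.205 to 0.490). Immediate early genes (median -0.62, 11 of 20 lower, 2 higher), which also respond to tissue dissociation, included Fos at 0.340 (0.274 to 0.425) and Egr1 at 0.234 (0.159 to 0.350). The 4 lowest genes by the naming rule were Cbr2, at 2 UMIs against 10 (42.7-fold lower, 9.10 to 401), the platelet factor Pf4 (17.5-fold lower, 10.02 to 31.5), the prostaglandin-degrading Hpgd (8.54-fold lower, 4.82 to 15.1) and Tapbpl (6.88-fold lower, 5.41 to 8.73). Cbr2 and Pf4 are known from resident macrophages. Tapbpl was lower in every class compared and in the free RNA, the RNA of near-empty droplets, at 1111 CPM in the naive and 232 CPM in the infected library.

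Classical monocyte-like cells (79 naive, 167 infected) had a median log2 ratio of 1.64 for interferon-gamma-induced genes, with 9 of 10 members higher and none lower. Examples were the guanylate-binding protein gene Gbp2 (8.16-fold, 2.16 to 69.1), Irf1 (3.79-fold, 1.39 to 14.4) and Ifi47 (3.69-fold, 1.62 to 10.4). Antigen presentation went the same way: MHC class I had a median of 0.78 (12 of 16 higher; H2-K1 1.72-fold, 1.41 to 2.13; Psmb9 1.99-fold, 1.17 to 3.60), and MHC class II 0.70 (6 of 10 higher, 1 lower; H2-DMb1 3.34-fold, 1.69 to 7.50; H2-Eb1 1.81-fold, 1.30 to 2.58; H2-Ab1 1.62-fold, 1.29 to 2.06). The type I interferon list, by contrast, had a median of -0.09 (5 higher and 5 lower of 22). The other genes named by the rule were Nampt, a NAD synthesis enzyme (14.6-fold, 2.499 to 587; 50 against 1 UMI), the iron-homeostasis gene Hfe (12.2-fold, 2.08 to 495) and the inhibitory receptor Lair1 (7.43-fold, 1.955 to 63.0), all higher. Lower were Rbks (1 against 15 UMIs; 51.5-fold lower, 7.92 to 2166), the lysozyme Lyz1 (6.67-fold lower, 3.68 to 12.5), Tapbpl (5.44-fold lower, 3.997 to 7.45) and Glrx3 (5.43-fold lower, 2.503 to 12.3). Lyz2 and F13a1, both strong monocyte genes, stood at 0.284 (0.2704 to 0.299) and 0.414 (0.335 to 0.511). At a clustering resolution of 2, 27 of the infected cells and 1 of the naive cells fell with non-classical monocyte-like cells, so a change in the mix was not separated. Ccr2 was 1483 CPM (1274 to 1717) in naive and 1249 CPM (1144 to 1361) in infected classical monocyte-like cells, and 78.5% and 84.4% of them held a Ccr2 UMI (54.4% and 46.1% after thinning, median depth 1262 and 2287 UMIs). Neutrophil genes were higher in this class (11 of 13 higher, median 1.72; S100a8 7694 against 2221 CPM), while S100a8 in the free RNA was 14165 against 55025 CPM.

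T cell-like cells (80 naive, 254 infected, clusters 4 and 7) held more of the type I interferon response after infection: 17 of 18 members were higher and 1 lower, with a median log2 ratio of 1.42. The makeup of the class differed as well, with CD4 T cell markers at 1605 CPM (1465 to 1756) in infected and 2411 CPM (2101 to 2753) in naive cells, CD8 T cell markers at 4883 CPM and 4799 CPM, and a CD3 UMI in 66.1% and 71.3% of cells (42.5% and 53.8% after thinning, median depths 1067.5 and 1046 UMIs). The CD8 T cell list includes Ccl5, so its sum does not measure CD8 T cells alone. At a clustering resolution of 2, 44 of the naive and 125 of the infected cells fell in a cluster that met no naming rule. Ifi27l2a stood at 1304 against 487 CPM (2.68-fold, 1.959 to 3.75), the ubiquitin-like Isg15 was 5.001-fold (1.28 to 43.0) and the tethering factor Bst2 2.42-fold (1.16 to 5.86) higher. Interferon-gamma-induced genes had a median of 0.77 (8 of 14 higher, 2 lower), cell cycle genes 0.95 (6 of 10 higher, 2 lower; Hmgb2 1.90-fold, 1.26 to 2.96) and cytotoxic effector genes 0.37 (6 of 15 higher, 2 lower; the chemokine Ccl4 6.74-fold, 2.54 to 25.3). Genes of naive and recirculating lymphocytes had a median of -0.49 (5 of 12 lower, 1 higher). Among them were Lef1 at 0.551 (0.320 to 0.974), Klf2 at 0.5997 (0.418 to 0.871) and Satb1 at 0.613 (0.419 to 0.910). The rule also named Esyt2 (34 UMIs against 0, at least 3.43-fold), Asxl2 (32 against 0, at least 3.23-fold), Gbp7 and Nfkbiz (each 10.9-fold, 1.84 to 443, on 36 UMIs against 1) as higher. Lower were Dapl1 (7.92-fold, 3.65 to 18.6), the diacylglycerol kinase Dgka, known to restrain T cell receptor signalling (4.80-fold, 2.09 to 11.4), and Chmp3 and Igbp1 (each 4.54-fold, 1.66 to 12.99).

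Microglia-like cells (cluster 11; 62 naive, 125 infected) had a median log2 ratio of -0.70 for the disease-associated microglia list, with 11 of 17 members lower and none higher. Apoe stood at 0.222 (0.195 to 0.252), Cd9 at 0.388 (0.324 to 0.465), the cathepsin Ctsz at 0.613 (0.509 to 0.740) and the signalling adaptor Tyrobp at 0.657 (0.577 to 0.750). Immediate early genes had a median of -0.46 (8 of 20 lower, 1 higher; Jun 0.436, 0.339 to 0.563). Homeostatic microglia genes had a median of -0.29 (3 of 16 lower, 1 higher), and NF-kB genes -0.07. Named as higher were Gbp7 and Fes (each 26 UMIs against 0, at least 3.01-fold) and Paqr7 and Mvp (each 23 against 0, at least 2.67-fold). Named as lower were Zmym2 (14.4-fold, 3.06 to 135), Vwa1 (11.5-fold, 3.10 to 63.5), Txnl4a (11.5-fold, 2.29 to 111) and the heat-shock gene Hspa1a (7.74-fold, 3.995 to 15.9), of which Zmym2, Vwa1 and Txnl4a rest on 2 or 3 UMIs in the infected cells.

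Neutrophil-like cells (clusters 0, 12 and 16; 273 naive, 175 infected) held more interferon-gamma-induced (5 of 5 higher, median 1.23; Irf1 2.34-fold, 1.13 to 5.02) and MHC class I genes (8 of 16 higher, none lower, median 0.52) after infection. H2-K1 was 2.42-fold (1.94 to 3.03) and the peptide-loading gene Tapbp 3.49-fold (1.961 to 6.51) higher. MHC class II genes were higher in 7 of 7 (median 1.42; H2-Ab1 4.11-fold, 2.63 to 6.59), and H2-Ab1 in the free RNA was 2046 against 1207 CPM. Granule genes had a median of -0.38 (1 of 10 lower; the cathelicidin Camp 0.653, 0.633 to 0.673) and glycolysis genes -0.39 (5 of 12 lower, 1 higher). The inflammatory genes Il1b and Cxcl2 stood at 0.404 (0.259 to 0.614) and 0.477 (0.385 to 0.588). Beside Tapbp, the rule named Eif2s2 (2.85-fold, 1.62 to 5.197), the secretory regulator Xbp1 (2.44-fold, 1.38 to 4.44) and Rassf5 (2.15-fold, 1.45 to 3.22) as higher. Lower were Mien1 (5.09-fold, 2.28 to 13.3), Tapbpl (3.93-fold, 2.88 to 5.47), Lyz1 (3.70-fold, 1.78 to 8.63) and the mitochondrial pyruvate carrier Mpc1 (3.18-fold, 1.79 to 6.02).

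B cell-like cells (146 naive, 277 infected) held more interferon-gamma-induced and lysosome transcripts after infection. At a clustering resolution of 2, 1 B cell-like cluster had 52 of the naive and 53 of the infected cells, and another had 82 and 210. Changes within a cell type were thus not separated from changes in the mix. Interferon-gamma-induced genes had a median log2 ratio of 0.62 (6 of 10 higher, 1 lower; Irf1 6.62-fold, 1.66 to 57.5; Irgm1 3.93-fold, 1.19 to 20.4) and lysosome genes 0.49 (7 of 15 higher, 2 lower; Psap 2.31-fold, 1.73 to 3.12). MHC class II genes had a median of -0.10 with all 12 members within 1.5-fold, and B cell activation genes -0.10 (3 higher and 2 lower of 8). Named as higher were Cd83, an activation marker (5.30-fold, 2.14 to 17.0), B4galnt1 (4.66-fold, 1.68 to 18.0), Ssr3 (3.68-fold, 1.57 to 10.6) and Lmbrd1 (3.43-fold, 1.34 to 11.2). Named as lower were Vwa1 (6.93-fold, 2.45 to 24.0), Marf1 (5.53-fold, 2.23 to 15.6), Tapbpl (4.71-fold, 3.25 to 6.93) and Ilf2 (3.52-fold, 1.59 to 8.19).

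A few lists moved with the free RNA in classes that do not normally express them. Retnla in the free RNA was 961 CPM in the infected and 6.11 CPM in the naive library, and the alternative activation list had medians of 1.74 in T cell-like, 1.11 in B cell-like and 2.02 in microglia-like cells. S100a8 in B cell-like cells had a ratio of 0.488 (0.423 to 0.564), with neutrophil genes at a median of -0.97 there and -1.06 in T cell-like cells. A TMM scaling would add 0.19 to log2 ratios in B cell-like cells, 0.17 in T cell-like and 0.19 in dendritic cell or macrophage-like cells, so medians nearer 0 than that have no clear direction. Classes with under 100 cells in a library (T cell-like, classical monocyte-like, dendritic cell or macrophage-like and microglia-like) were compared on a lower minimum set after the data were seen.

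**Figure D2:**
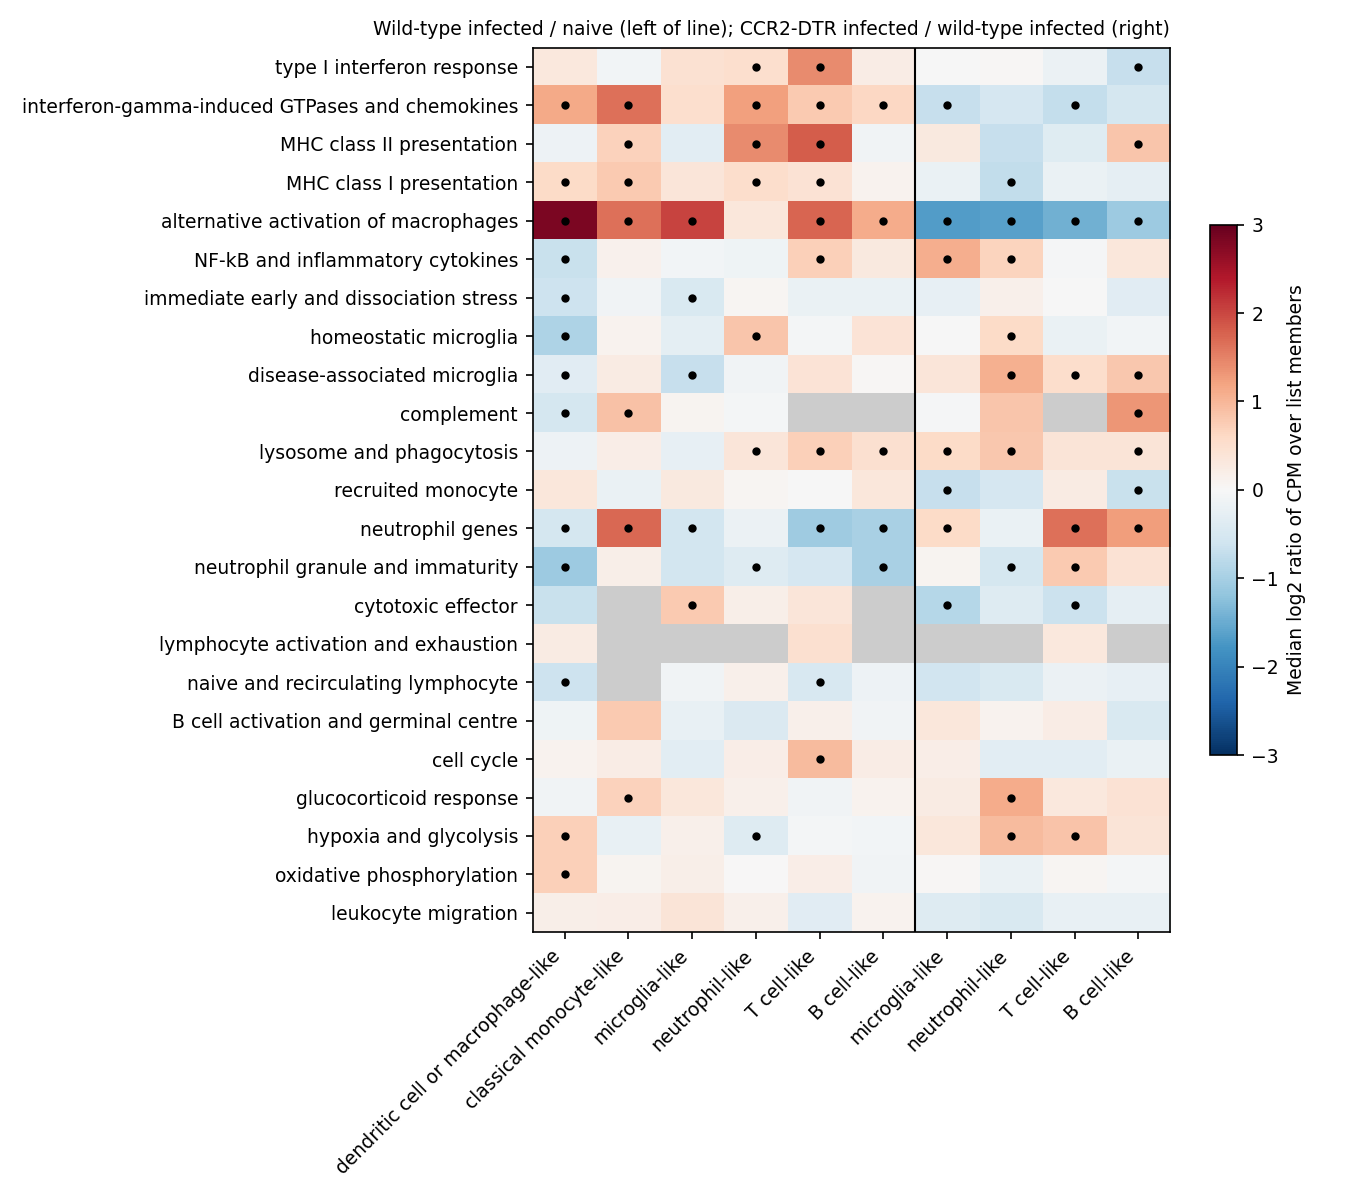
Median log2 ratio of each gene list in each compared class, with infection to the left and depletion to the right of the line. Dots mark medians outside the central 95% of matched random lists, and grey marks lists with under 5 measured members.

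The second comparison, CCR2-DTR infected against wild-type infected, asks what the brain leukocytes of infected mice look like without monocytes. Monocyte-like and dendritic cell or macrophage-like cells were nearly absent from the CCR2-DTR library, and Gata3 and Il1rl1 lymphocyte-like and natural killer cell-like cells had smaller shares. Neutrophil-like cells took 30.5% of the library and carried a different set of transcripts, with Wfdc17 at 17275 against 576 CPM and Ifitm1 at 5470 against 169 CPM. T cell-like cells held less granzyme A and fewer interferon-gamma-induced transcripts but more of the glycolysis genes, and B cell-like cells more MHC class II. Microglia-like cells held more of the NF-kB and inflammatory cytokine list, Ccl2, Ccl3 and Ccl12 included, and less of the interferon-gamma-induced one. The wild-type infected library is the numerator of the first comparison and the denominator here, so any error in it enters both with opposite sign.

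Classical monocyte-like cells were 9.28% (7.98 to 10.7) of the wild-type infected and 0.167% (0.0344 to 0.487) of the CCR2-DTR infected library, from 167 and 3 cells, a share 55.6-fold lower (18.7 to 273). The log2 ratio of -5.80 became -4.22 at a limit of 20% mitochondrial UMIs. Non-classical monocyte-like cells were 131 and 1 (131-fold lower, 23.1 to 5210), and dendritic cell or macrophage-like cells 299 and 6 (16.6% and 0.334%; 49.8-fold lower, 22.6 to 137). The log2 ratio of the dendritic cell or macrophage-like share was -5.64 here but lay from -7.10 to -8.25 with other UMI minimums, mitochondrial limits or clustering resolutions and with doublets kept, and was -5.67 with 20 principal components and another seed. A smaller loss, -4.72, was seen without neutrophil-like cells and cluster 14. At a clustering resolution of 2, 5 of the 6 cells (median depth 889 UMIs) fell in a cluster named choroid plexus or ependymal cell-like, with Ttr as a top gene, and 1 stayed in the class. The printed fold thus rests on a few cells of uncertain type. Gata3 and Il1rl1 lymphocyte-like cells were 141 and 19 (7.42-fold lower, 4.58 to 12.7; log2 ratio -2.89, against -1.97 without neutrophil-like cells and cluster 14 and -2.09 with doublets kept), natural killer cell-like cells 108 and 26 (4.15-fold lower, 2.69 to 6.64), and basophil or mast cell-like cells 38 and 7 (5.43-fold lower, 2.39 to 14.4). Without neutrophil-like cells and cluster 14 the log2 ratio was -1.52 in place of -2.44 for basophil or mast cell-like, -4.88 in place of -5.80 for classical and -6.12 in place of -7.03 for non-classical monocyte-like cells. Plasmacytoid dendritic cell-like cells were 9 and 0, with an upper limit of 0.205% in the CCR2-DTR library. Among the named classes of the wild-type infected library, those above were also the ones with most Ccr2. It stood at 893 CPM in dendritic cell or macrophage-like, 617 in non-classical monocyte-like and 517 in basophil or mast cell-like cells. Values were 494 in plasmacytoid dendritic cell-like, 339.5 in Gata3 and Il1rl1 lymphocyte-like and 247 in natural killer cell-like cells. They were 137 in T cell-like, 91.7 in microglia-like, 70.6 in neutrophil-like and 43.0 in B cell-like cells. The unnamed clusters 6 and 14 were left out of this ranking. Cluster 6 was also lower, at 2.06% and 0.389%, from 37 and 7 cells, a ratio of 0.189 (0.0712 to 0.430). The match of loss to Ccr2 thus covers named classes only. The 3 classical monocyte-like cells left in the CCR2-DTR library still held 8 Ccr2 UMIs.

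**Figure D3:**
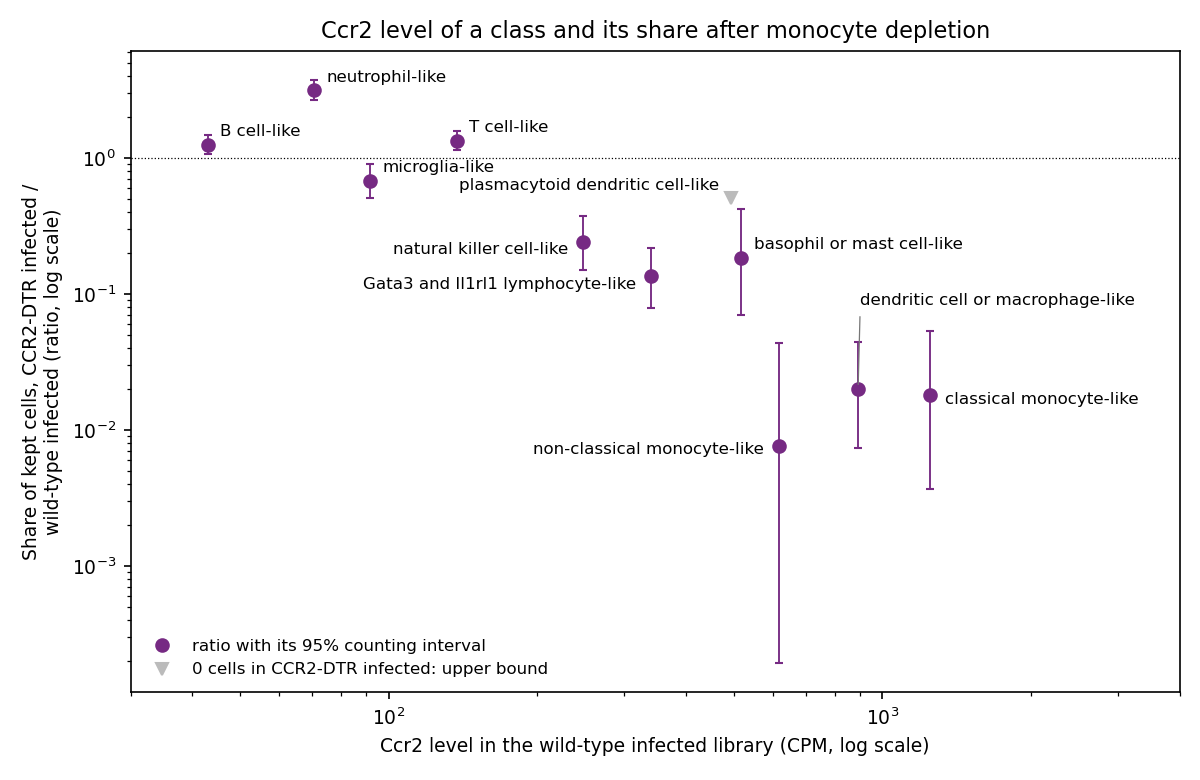
Ccr2 level of each class in the wild-type infected library against the share of that class in the CCR2-DTR infected relative to the wild-type infected library, both on log scales. Bars are 95% intervals covering counting error only, and the triangle is an upper bound from 0 cells.

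Neutrophil-like cells were 9.72% (8.39 to 11.2) of the wild-type infected library, with 159, 7 and 9 cells in clusters 0, 12 and 16. They were 30.5% (28.4 to 32.7) of the CCR2-DTR infected library, with 8, 92 and 449 cells in those clusters, a ratio of 3.14 (2.64 to 3.74). The log2 value of this ratio, 1.65, became 2.28 at a clustering resolution of 2. B cell-like cells were 15.4% and 19.2% (1.25, 1.06 to 1.47), T cell-like cells 14.1% and 18.9% (1.34, 1.14 to 1.58) and microglia-like cells 6.94% and 4.72% (0.680, 0.510 to 0.903). Cluster 14 was 2.17% and 22.8% (10.5, 7.56 to 15.01), and as 410 of its 457 cells came from 1 library it may stand for that library rather than for a cell type. At a clustering resolution of 2 its cells of the CCR2-DTR library fell into 2 clusters: 272 cells (median depth 807 UMIs) that stayed unnamed, with C1qb and C1qa as top genes, and 138 cells (2555.5 UMIs) that met the naming rule for microglia, with Gadd45b and Il1a. The directions for T cell-like and microglia-like shares were not stable. The T cell-like log2 ratio of 0.42 became -0.03 with a minimum set from the 99th percentile of depth. With that minimum no Gata3 and Il1rl1 lymphocyte-like cluster formed, and a T cell-like cluster had Gata3 and Il1rl1 among its top genes. That value thus covers a different set of cells. The microglia-like log2 ratio of -0.56 became 0.87 at a clustering resolution of 2. With a minimum of 1000 UMIs the log2 ratio of natural killer cell-like cells was -1.10 in place of -2.05, that of B cell-like cells 1.16 in place of 0.32, and that of T cell-like cells 0.97.

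Neutrophil-like cells of the CCR2-DTR library (549 against 175 cells) were in large part a separate cluster, 16, so this contrast is also one between clusters. Within cluster 16, where the wild-type infected library had 9 cells, Wfdc17 stood at 24325 CPM (24062 to 24591) against 5981 CPM (4362 to 8003) and Ifitm1 at 7542 CPM (7396 to 7691) against 1462 CPM (729.8 to 2616), smaller differences than over the whole class. Within cluster 0, where the CCR2-DTR library had 8 cells, Wfdc17 differed more, at 18105 CPM (15776 to 20680) against 450 CPM (365 to 550), and Ifitm1 stood at 1585 CPM (954 to 2475) against 145 CPM (98.8 to 206). Within cluster 12 (92 and 7 cells) Wfdc17 stood at 1152 CPM (1067 to 1242) against 175 CPM (64.1 to 380). The acute-phase gene Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) was 107-fold higher (19.2 to 4233; 813 UMIs against 1), the interferon-inducible Ifitm1 32.4-fold (24.1 to 44.9) and Wfdc17 (ENSMUSG00000069792, chromosome 11, 83703991 to 83706268) 29.97-fold (25.5 to 35.5). Stfa2, a stefin protease inhibitor, had 485 UMIs against 0 (at least 21.3-fold). Within cluster 16, Stfa2 stood at 353 CPM and Saa3 at 596 CPM in the CCR2-DTR library, against 0 UMIs with an upper limit of 490 CPM in the 9 wild-type infected cells, so the folds of these 2 genes over the class were not separated from the mix of clusters. Glucocorticoid response genes had a median log2 ratio of 1.11 (7 of 11 higher, 1 lower), above 99.98% of matched random lists, but 0.49 without the filter on low levels, 0.70 with doublets kept and 1.59 with a minimum of 1000 UMIs. Among them were Mt1 at 8.82-fold (4.44 to 20.5), Tsc22d3 at 2.43-fold (1.80 to 3.36) and Dusp1 at 2.18-fold (1.84 to 2.60). Glycolysis genes had a median of 0.96 (8 of 12 higher, 1 lower; Ldha 2.93-fold, 2.21 to 3.97; Aldoa 2.90-fold, 2.24 to 3.84; Gapdh 2.40-fold, 1.999 to 2.91). NF-kB and inflammatory cytokine genes had a median of 0.67 (9 of 16 higher, 5 lower), with Cd14 at 15.2-fold (7.35 to 38.0), the neutrophil-attracting Cxcl2 at 4.73-fold (3.96 to 5.70) and Il1b at 3.12-fold (2.17 to 4.66). Il1r2, the decoy receptor for IL-1, was 6.17-fold higher (4.25 to 9.33).

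Several genes of granules and antigen presentation were lower in the neutrophil-like cells of the CCR2-DTR library. The granule list had a median of -0.52 (6 of 12 lower, 2 higher), with lactoferrin, Ltf, at 0.269 (0.254 to 0.284), Camp at 0.378 (0.367 to 0.389), Mmp9 at 0.425 (0.384 to 0.471) and the oxidase subunit Cybb at 0.261 (0.225 to 0.303). MHC class I genes had a median of -0.74 (9 of 16 lower, 2 higher; H2-K1 0.293, 0.251 to 0.344). Migration genes had a median of -0.45 (4 of 11 lower, 1 higher), and the marrow-retention receptor Cxcr4 stood at 0.216 (0.169 to 0.279). The rule named as lower Thbs1 (38.5-fold, 21.5 to 74.0), Stk39 (9.21-fold, 5.66 to 15.1), Arhgap4 (6.61-fold, 3.80 to 11.5) and the calcium pump Atp2a3 (6.53-fold, 4.24 to 10.02). Neutrophil identity genes as a list had a median of -0.20 (3 of 14 lower, 2 higher), and S100a8 a ratio of 0.810 (0.804 to 0.818). Lysosome genes (median 0.81, 10 of 18 higher, 2 lower; Ctsd 2.43-fold, 2.02 to 2.97) and disease-associated microglia genes (median 1.08) were higher too, as were Ctsd (3318 against 1401 CPM) and C1qa (2749 against 558 CPM) in the free RNA. A TMM scaling would add 0.42 to every log2 ratio in this class, so the directions of the migration and neutrophil identity lists are not clear, and the granule list stands near 0 under that scaling.

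T cell-like cells (340 against 254) held less of 2 effector groups in the CCR2-DTR library, and the makeup of the class differed as well. A CD3 UMI was seen in 91.8% (88.3 to 94.5) against 66.1% (59.96 to 71.9) of cells (61.5% against 42.5% after thinning, median depths 2153 and 1067.5 UMIs). CD4 T cell markers stood at 2365 CPM (2264 to 2470) against 1605 CPM (1465 to 1756), and CD8 T cell markers at 4353 CPM (4215 to 4494) against 4883 CPM (4636 to 5141). The CD8 T cell list includes Ccl5, which was itself lower here, so its sum does not measure CD8 T cells alone. At a clustering resolution of 2, the 3 T cell-like clusters had 163, 79 and 48 cells of the CCR2-DTR library against 21, 6 and 84. Of the 163, 5 came from the Gata3 and Il1rl1 lymphocyte-like class, and of the 48, 4 came from the natural killer cell-like class. Of the 340 and 254 T cell-like cells, 57 and 125 fell in a cluster that met no naming rule. Interferon-gamma-induced genes had a median log2 ratio of -0.72 (9 of 14 lower, 3 higher; Gbp7 0.491, 0.314 to 0.775; Igtp 0.526, 0.322 to 0.872), and cytotoxic effector genes -0.64 (7 of 14 lower, 2 higher). Granzyme A, Gzma, was 10.96-fold lower (7.85 to 15.6; 52.3 against 573 CPM), the chemokines Ccl4 and Ccl5 stood at 0.241 (0.172 to 0.338) and 0.571 (0.528 to 0.619), and Xcl1 at 0.371 (0.214 to 0.645). Natural killer cell-like cells, clustered apart, held a CD3 UMI in 46.2% of 26 cells of the CCR2-DTR library (30.8% after thinning, median depth 2146.5 UMIs) and in 6.48% of 108 cells of the wild-type infected one (3.70% after thinning, median depth 924 UMIs). B cell-like cells held one in 7.23% and 4.33% (2.60% and 1.81% after thinning, median depths 1393 and 852 UMIs), so which cytotoxic cells were counted as T cell-like may differ between the libraries. The type I interferon list had a median of -0.18 (5 of 19 lower, 3 higher). Glycolysis genes were higher in 8 of 12 and lower in 2 (Eno1 3.95-fold, 2.68 to 6.04; Gapdh 3.29-fold, 2.44 to 4.53; Ldha 2.73-fold, 2.01 to 3.78). Of the activation list, 5 of 11 members were higher and 3 lower (median 0.31), including the early activation marker Cd69 at 2.37-fold (1.61 to 3.60). The rule named Dapl1 (6.76-fold, 3.60 to 14.3), the costimulatory receptor Tnfrsf4 (5.25-fold, 2.46 to 13.4), Ube2n (5.15-fold, 2.41 to 13.1) and Sep15 (4.76-fold, 2.82 to 8.66) as higher, and all 4 were also higher in the free RNA (Dapl1 24.5 against 1.63 CPM, Tnfrsf4 50.2 against 39.04 CPM, Ube2n 87.8 against 48.3 CPM, Sep15 416 against 152 CPM). Beside Gzma, the lower genes were Tsix (6.58-fold, 4.29 to 10.3), the integrin gene Itgal (4.84-fold, 3.69 to 6.39) and Gins1 (4.44-fold, 3.37 to 5.89). All 4 were also lower in the free RNA: Gzma 164 against 604 CPM, Tsix 10.2 against 40.1 CPM, Itgal 109 against 688 CPM and Gins1 35.2 against 168 CPM. Tsix was lower in microglia-like cells as well. The cytotoxic median changed direction, to 0.11, with the minimum set from the 99th percentile of depth. There the T cell-like class included a cluster with Gata3 and Il1rl1 among its top genes, so it held different cells. The interferon-gamma median was -0.24 with called doublets kept.

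B cell-like cells (346 against 277) held more MHC class II in the CCR2-DTR library: 7 of 12 members were higher and 2 lower, with a median log2 ratio of 0.84. At a clustering resolution of 2 these cells split nearly by library, so this is also a contrast between B cell clusters. A cluster with Cd74 and H2-DMb2 among its top genes had 284 of these cells from the CCR2-DTR and 14 from the wild-type infected library. The other 2 had 50 and 12 of them against 210 and 53. The invariant chain gene Cd74 was 2.54-fold (2.42 to 2.66), H2-Aa 1.97-fold (1.80 to 2.16), H2-Ab1 1.89-fold (1.72 to 2.07) and H2-Eb1 1.71-fold (1.54 to 1.90) higher, while H2-Aa in the free RNA was lower in that library. Type I interferon response genes had a median of -0.70 (10 of 14 lower, none higher), with Ifi27l2a at 0.400 (0.334 to 0.478). B cell activation genes had a median of -0.46 (4 of 7 lower, none higher). The glucocorticoid-induced Tsc22d3 was 2.79-fold higher (2.26 to 3.46). Also named as higher were Plp2 (7.48-fold, 2.78 to 28.3), Lamtor5 (5.60-fold, 2.27 to 17.9), the ubiquitin gene Ubb (4.24-fold, 3.50 to 5.16) and Apoe (3.95-fold, 3.16 to 5.004), all 4 of them also higher in the free RNA (Plp2 62.7 against 26.6 CPM, Lamtor5 119 against 87.8 CPM, Ubb 2236 against 498.9 CPM, Apoe 2316 against 1093 CPM). Named as lower were Tnks2 (4.79-fold, 2.60 to 9.22), Clec2d (4.58-fold, 3.16 to 6.72) and Ddx6 (4.001-fold, 2.75 to 5.90). All 3 were also lower in the free RNA: Tnks2 40.6 against 139 CPM, Clec2d 94.99 against 532 CPM and Ddx6 141 against 364 CPM.

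Microglia-like cells (cluster 11; 85 against 125) held more NF-kB and inflammatory cytokine transcripts in the CCR2-DTR library, with 11 of 17 members higher and 2 lower, a median log2 ratio of 1.10. Cluster 14, which also held microglial transcripts, is not in this class and had 410 cells of the CCR2-DTR against 39 of the wild-type infected library. At a clustering resolution of 2, 138 of these 410 were named microglia-like. The values here thus cover only part of the cells with microglial transcripts. The monocyte-attracting chemokine Ccl2 was 3.79-fold (3.07 to 4.72), Ccl3 2.55-fold (2.097 to 3.13) and Ccl12 2.14-fold (1.92 to 2.40) higher, and the NF-kB inhibitor Nfkbia 2.36-fold (1.75 to 3.22). Lysosome genes had a median of 0.57 (10 of 20 higher, 5 lower; Ctsz 2.22-fold, 1.95 to 2.53; Ctsl 1.98-fold, 1.68 to 2.34). The homeostatic list had a median of -0.01, within which the fractalkine receptor Cx3cr1 stood at 0.654 (0.578 to 0.740) and the microglial transcription factor Sall1 at 0.437 (0.268 to 0.698). Apoe (2.78-fold, 2.48 to 3.11) and Trem2 (1.74-fold, 1.503 to 2.02) were higher, in a disease-associated list with a median of 0.35 (5 higher and 6 lower of 17). Interferon-gamma-induced genes had a median of -0.70 (8 of 12 lower, 1 higher), with Irf1 at 0.203 (0.0679 to 0.510). Named as higher were the nucleotide-synthesis enzyme Impdh2 (31 UMIs against 1; 25.2-fold, 4.20 to 1027), the stress gene Ddit4 (12.6-fold, 3.21 to 109), Oser1 (11.5-fold, 5.08 to 32.3) and Adap2os (7.06-fold, 4.20 to 12.7). Named as lower were Mga (14.8-fold, 3.67 to 129), Prkd3 (7.07-fold, 2.42 to 28.1), Tsix (6.50-fold, 4.05 to 10.9) and Lhfpl2 (6.15-fold, 2.31 to 20.6). This class had 85 cells in the CCR2-DTR library and was also compared on the lower minimum set after the data were seen.

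All genes named as highest or lowest in this comparison, in each of the 4 classes, differed in the same direction in the free RNA, which is made up in part of RNA from these cells. Neutrophil genes moved with the free RNA in the other classes of the CCR2-DTR library, with medians of 1.64 in T cell-like and 1.25 in B cell-like cells, while S100a8 in the free RNA was 60494 against 14165 CPM. The alternative activation list went the other way (T cell-like -1.43, B cell-like -1.09, microglia-like -1.67), with Retnla in the free RNA at 4.78 against 961 CPM. Scaling shifts beyond the neutrophil-like class were 0.20 for B cell-like, 0.12 for T cell-like and 0.11 for microglia-like cells under TMM.

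Set against the naive library directly, the CCR2-DTR infected library had a neutrophil-like share ratio of 0.988 (0.853 to 1.15), a T cell-like ratio of 2.09 (1.63 to 2.70) and a Gata3 and Il1rl1 lymphocyte-like ratio of 0.424 (0.217 to 0.822). The neutrophil-like cells came from clusters 12 and 16 in all but 8 of 549 cases in the CCR2-DTR library, and from cluster 0 in 251 of 273 cases in the naive one. T cell-like cells of the CCR2-DTR library had a type I interferon median log2 ratio of 1.38 against naive cells (14 of 16 higher, none lower) and a cytotoxic median of 0.16. Microglia-like cells had a disease-associated median of -0.70 and an NF-kB median of 0.72, and neutrophil-like cells a glucocorticoid median of 1.10 and a granule median of -0.95, each against the naive library. In B cell-like cells MHC class II had a median of 0.60 and the type I interferon list one of -0.75.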

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

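Each group had 1 library, so leaving out a replicate is not possible and biological spread is unknown. No paired analysis was possible because the 3 libraries came from separate mice with no shared donor, batch or day in the labels. All values here are log2 ratios, with the reported value first; the cause was not tested.

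Shares, CCR2-DTR against wild-type infected. Dendritic cell or macrophage-like: -5.64, against -7.41 at a minimum of 1000 UMIs, -7.10 with the minimum from the 99th percentile of depth, -7.97 at 5% and -7.27 at 20% mitochondrial UMIs, -8.25 with doublets kept, -8.23 at Leiden 0.5, -8.22 at Leiden 2 and -4.72 without neutrophil-like cells and cluster 14. Classical monocyte-like: -5.80, against -4.22 at 20% mitochondrial UMIs. Gata3 and Il1rl1 lymphocyte-like: -2.89, against -2.09 with doublets kept and -1.97 without neutrophil-like cells and cluster 14. Neutrophil-like: 1.65, against 2.28 at Leiden 2. T cell-like, with the sign turned: 0.42, against -0.031 with the percentile minimum, -0.11 with doublets kept and -0.12 at Leiden 0.5, but 0.97 at 1000 UMIs, 1.39 at Leiden 2 and 1.34 without neutrophil-like cells and cluster 14. Microglia-like, with the sign turned: -0.56, against 0.87 at Leiden 2 and 0.36 without neutrophil-like cells and cluster 14. Natural killer cell-like: -2.05, against -1.10 at 1000 UMIs and -1.14 without neutrophil-like cells and cluster 14. B cell-like: 0.32, against 1.16 and 1.24 in the same settings. Keeping doublets adds few cells, so those values come with a new clustering. With the percentile minimum and at Leiden 0.5 no Gata3 and Il1rl1 lymphocyte-like cluster formed, so the T cell-like class may hold other cells there.

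Shares, infected against naive. T cell-like: 0.64, against 0.027 at 1000 UMIs, 1.75 with doublets kept, 1.14 with 20 principal components and another seed and 0.26 without neutrophil-like cells. Gata3 and Il1rl1 lymphocyte-like: 1.65, against 0.96 with doublets kept. B cell-like: -0.10, against -0.47 with the percentile minimum, -0.44 at 20% mitochondrial UMIs and -0.49 without neutrophil-like cells.

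Lists, CCR2-DTR against wild-type infected. Glucocorticoid response in neutrophil-like cells: 1.11, against 1.59 at 1000 UMIs, 0.70 with doublets kept, 1.53 with TMM, 1.51 with median-of-ratios factors and 0.49 without the low-level filter. NF-kB in microglia-like cells: 1.10, against 1.27 at 5% mitochondrial UMIs and 1.31 with median-of-ratios factors. Interferon-gamma in T cell-like cells: -0.72, against -0.24 with doublets kept. Signs turned in T cell-like cells for cytotoxic (-0.64, against 0.11) and granule genes (0.78, against -0.0053) with the percentile minimum, for homeostatic microglia genes in neutrophil-like cells (0.58, against -0.047) on thinning, and for neutrophil genes in B cell-like (1.25, against -0.66) and microglia-like cells (0.57, against -1.08) once free RNA was subtracted.

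Lists, infected against naive. Alternative activation in dendritic cell or macrophage-like cells: 2.83, against 3.42 with a prior of 1 CPM. Type I interferon in T cell-like cells: 1.42, against 0.94 with the percentile minimum. Interferon-gamma in classical monocyte-like cells: 1.64, against 1.21 on thinning. Signs turned for T cell-like MHC class I (0.43, against -0.077) with the percentile minimum, T cell-like NF-kB (0.72) at 5% mitochondrial UMIs (-0.17) and with free RNA subtracted (-0.13), T cell-like lysosome genes (0.72, against -0.072) and microglia-like neutrophil genes (-0.54, against 0.45) with free RNA subtracted, homeostatic microglia genes in neutrophil-like cells (0.83, against -0.062) at 1000 UMIs, and recirculating lymphocyte genes in dendritic cell or macrophage-like cells (-0.62, against 0.12) on thinning.

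Over all settings, 676 list values stayed within their intervals, 127 moved and 12 turned sign from an interval that left out 0. For shares these were 153, 30 and 5, and for named genes 790 stayed and 50 moved. Of the 127, 1 also passed 0: disease-associated microglia genes in dendritic cell or macrophage-like cells, infected against naive. That value was -0.35, against 0.44 at 5% mitochondrial UMIs, from an interval that held 0. The 3 alternatives added after the data were seen are the minimum of 50 cells and the 2 sets of shares on fewer cells. Some settings gave no value: clusters of plasmacytoid dendritic cell-like and, in several, non-classical monocyte-like or Gata3 and Il1rl1 lymphocyte-like cells did not form, classes fell under 50 cells at 1000 UMIs, and lists fell under 5 members once free RNA was subtracted.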

Other observations

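All tests below were chosen after the result was seen, except those on the median of nuclear RNAs, on a shift shared by all classes and on depth per cell.

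Il4, Il5, Il13 and Areg were counted in every class and unnamed cluster of the wild-type infected library. Gata3 and Il1rl1 lymphocyte-like cells held Il5 at 98.2 CPM (68.4 to 137; 35 UMIs), Il13 at 61.7 CPM (38.7 to 93.5; 22 UMIs), Il4 at 47.7 CPM (27.8 to 76.4; 17 UMIs) and the tissue-repair factor Areg at 81.4 CPM (54.5 to 117; 29 UMIs). T cell-like cells, at 254 cells, held 0, 1, 1 and 0 UMIs of these genes, and no group other than the Gata3 and Il1rl1 lymphocyte-like and basophil or mast cell-like cells held more than 2 UMIs of any. The marker list that named the Gata3 and Il1rl1 lymphocyte-like class holds Il5, Il13 and Areg, so their place there follows in part from the clustering and naming. With 9 plasmacytoid dendritic cell-like cells and 0 UMIs, the upper limit there was 182 CPM. Il4 in the free RNA of that library was 36.9 CPM. Basophil or mast cell-like cells held Il4 at 242 CPM (136 to 400.0), with a UMI in 31.6% of 38 cells. A CD3 gene was seen in 69.5% of the Gata3 and Il1rl1 lymphocyte-like cells (36.2% after thinning, median depth 1918 UMIs), against 4.33% of B cell-like cells (1.81% after thinning, median depth 852 UMIs), so CD3 transcripts in this class went beyond those seen in a class that should lack them. In the 19 such cells of the CCR2-DTR infected library Il5 was 237 CPM (160 to 338; 30 UMIs) and Il13 had 0 UMIs, while the makeup of the class differed too: markers of type 2 innate lymphoid cells stood at 6018 CPM (5598 to 6461) against 2222 CPM (2070 to 2383) in the wild-type infected library, and CD4 T cell markers at 323 CPM (232 to 439) against 1271 CPM (1157 to 1394), with regulatory T cell markers at 1948 CPM (1713 to 2207) against 1428 CPM (1307 to 1558). T cell-like cells of the CCR2-DTR library held Il4 at 24.4 CPM (15.1 to 37.3; 21 UMIs).

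The makeup of the dendritic cell or macrophage-like class differed between the naive and the wild-type infected library. Markers of border-associated macrophages, the resident macrophages of meninges and vessels, stood at 1564 CPM (1327 to 1832) in naive and 579.6 CPM (529 to 633) in infected cells. Markers of mature migratory dendritic cells stood at 467 CPM (342 to 623) and 1846 CPM (1755 to 1940), and those of type 1 conventional dendritic cells at 945 CPM (763 to 1157) and 1375 CPM (1296 to 1456). Markers of type 2 conventional dendritic cells stood at 813 CPM (644 to 1011) and 939 CPM (875 to 1007). Those of monocyte-derived macrophages or dendritic cells, the list that named cluster 10, stood at 22033 CPM (21116 to 22981) and 6273 CPM (6105 to 6445). That list includes Apoe, C1qa and C1qb, all lower in the infected cells of this class, and Apoe was also lower in microglia-like cells. A change in the share of monocyte-derived cells was thus not separated from lower levels of these genes. In T cell-like cells Dapl1 followed no single direction over the 3 libraries, at 265 CPM in the naive, 33.5 CPM in the wild-type infected and 227 CPM in the CCR2-DTR infected library. Gzma in natural killer cell-like cells stood at 7589, 10186 and 10480 CPM in the same order. The CD8 T cell marker list stood at 19614, 13298 and 25886 CPM in this class. That list includes Ccl5, a top gene of the natural killer cell-like cluster, so its sum does not measure CD8 T cells there.

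Classes with Ccr2 other than classical monocyte-like cells were few in the CCR2-DTR library. Against B cell-like cells, 5 such classes stood at 0.171 cells per B cell-like cell in that library and 2.59 in the wild-type infected one, a ratio of 0.0659 (0.0484 to 0.0897), which excludes dilution by neutrophil-like cells and cluster 14. Cells lost below the minimum cannot be told apart from absent ones: marker UMIs in the 1115 barcodes from 100 UMIs up to it allow at most 0.182 (upper limit 0.425) of the missing non-classical monocyte-like, 0.306 (upper limit 0.395) of natural killer cell-like, 2.83 of dendritic cell or macrophage-like, 1.06 of Gata3 and Il1rl1 lymphocyte-like and 3.45 of basophil or mast cell-like cells. The low values rest on the marker share of kept cells and leave out shallower barcodes. With all barcodes below the minimum and the marker share of the shallowest kept cells, the upper limits are 2.43 and 3.73 for the first 2. With every other UMI taken as free RNA and the largest depth below the minimum per cell, the 5 values in the same order are -0.0194, -0.0603, 0.0952, -0.126 and 0.105. A loss that follows the Ccr2 level of a class remains possible. Ccr2 and the share ratio had a rank correlation of -0.818 over 11 named classes, and -0.830 without classical monocyte-like cells. The unnamed clusters 6 and 14, with share ratios of 0.189 and 10.5, were left out of it. This correlation restates the pattern over the same classes, and shares of 1 library are not independent, so it adds no separate support. Ccr2 protein on each class by flow cytometry before and after depletion would test such a loss.

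Cluster 14 held microglial transcripts with little Malat1 and came mostly from the CCR2-DTR library, where a clustering resolution of 2 split it into 272 shallow and 138 deeper cells with Malat1 at 0.0481 (0.0433 to 0.0533) and 0.214 (0.205 to 0.224) of its level in cluster 11. If these droplets held cytoplasm with little nuclear RNA, other nuclear RNAs would be low too: of 7 not looked at before, Neat1 stood at 0.164 (0.110 to 0.239), Kcnq1ot1 at 0.0873 (0.0215 to 0.265) and Tsix at 0.187 (0.0786 to 0.415) of cluster 11, and the sum at 0.224 (0.170 to 0.295), but the median of 0.785, set by 4 RNAs with 5 or fewer UMIs there, decided nothing, so this cannot be told apart from a microglial state with less of these RNAs. Free RNA alone is excluded, since S100a8 in cluster 14 was 0.0976 (0.0947 to 0.101) of its free-RNA level. Activated microglia may also lie behind it, as NF-kB genes in cluster 11 had a median log2 ratio of 1.10 (0.82 to 1.25), but this cannot be told apart from a difference between libraries, and a CD45hi sort leaves out most microglia, which normally carry less CD45. Staining of intact cells for C1q and a microglial marker would test it.

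Neutrophil-like cells of the CCR2-DTR library held more Wfdc17, Ifitm1, Stfa2 and Saa3. Free RNA enters droplets of every class. In B cell-like and T cell-like cells of that library the 4 genes had a median of 0.0403 (range 0 to 0.0571, highest upper limit 0.0921) times their level in neutrophil-like cells. The naming rule already asked for at least 0.5 times the free-RNA level, so a low ratio was largely set in advance. Levels in neutrophil-like cells stood above the free RNA itself, at 17275 against 7263 CPM for Wfdc17, 5470 against 2766 for Ifitm1, 250 against 53.8 for Stfa2 and 420 against 275 for Saa3. Free RNA alone would not exceed its own level. Thinning every cell to the same depth left 0.944 of the median log2 ratio of the 4 genes (4.63 against 4.91). The difference thus did not rest on deeper cells weighing more in the summed counts. Random thinning leaves the expected level within each cell unchanged, so the test cannot decide whether depth affected which cells were kept or how they clustered. A shift shared by all classes could contribute and cannot be told apart. Over 26 of the 43 genes at least 4-fold higher, T cell-like cells had 0.534 of the shift in neutrophil-like cells (1.11 against 2.09). Resampling the 26 genes gave a range of 0.423 to 0.626, which is not a counting interval. Free RNA was subtracted from the T cell-like but not from the neutrophil-like counts in this test. Replicate libraries of each genotype would separate genotype from library.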
